A study of Mus musculus with 19 samples.

How the data were processed

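The data were 19 one-colour Agilent microRNA (miRNA) arrays, each hybridized with liver RNA of 1 mouse. Per the labels' protocols, male MutaMouse animals of 10 weeks were gavaged daily for 28 days with dibenz[a,h]anthracene in olive oil or with olive oil alone, and liver was taken 3 days after the last dose. Total RNA with its small fraction was isolated with the mirVana kit, and 100 ng was labelled with Cyanine 3-pCp, per the labels. The controls and the groups given 6.25 and 25 mg/kg/day had 5 arrays each. The labels describe 5 animals per dose, and 4 arrays of the group given 12.5 mg/kg/day were analysed here. The arrays lay on 3 slides, each of which held all 4 groups. Slide 1 carried 1 control, 1 low dose, 2 middle dose and 2 high dose arrays. Slide 2 carried 1, 2, 1 and 2 arrays of these groups, and slide 3, scanned later, carried 3, 2, 1 and 1. For arrays like these, the number of arrays limits the precision.

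Per the file headers, spots were read and background-subtracted with Agilent Feature Extraction 10.7.3.1, which gave 1 signal intensity per spot with no scaling between arrays. Such an intensity can be negative. The value table of the series held 692 miRNAs on the log2 scale, as the authors deposited it, and 636 of its names were matched to the scanner files. A comparison with the scanner files showed that each column followed the log2 raw median signal of its array. The medians of its columns lay between 5.04 and 5.05, a little above column minima of 4.85 to 4.92. Of 696 miRNAs 453 were detected on no array, so these medians may be background levels. Whether detected miRNAs had been set to a common level was not tested, and the method used for the table is not given in the sources used here.

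From the scanner files, 13920 of 14635 spots per array were used after control spots were removed, and spots that the scanner software had marked as outliers were left out. The 5 to 20 spots of each of 1937 probes were averaged. Each array was divided by its 75th percentile over the 220 probes detected on all arrays. Values under a floor of -4.79 on the log2 scale, set from the lowest scaled signals well above background, were raised to it, so levels at the floor have no order among themselves. A miRNA was represented by its brightest probe, and 1 to 4 probes stood for each miRNA. Of 696 miRNAs on the array, 208 were detected on at least 4 arrays and were tested, 137 were detected on all arrays and 453 on none. There were 0 saturated spots.

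Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the slide as a fixed block and 1 estimate of the spread over all groups. There were 6 tests across miRNAs: each dose against control, an F test for any difference among the 4 groups, a linear trend over the dose in mg/kg/day, and the mean of the 3 doses against control. All tests were two-sided except the F test, with Benjamini-Hochberg adjusted p under 0.05 within each test. Standard errors (SE) and intervals of fold changes came from limma, with a confidence level of 95%. Signal measures of whole arrays and miR-34a were also compared with exact permutation tests, two-sided.

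The fixed lists covered the p53 response, hepatocytes, the aryl hydrocarbon receptor, the let-7 family, the miR-17 clusters, liver tumours, the Dlk1-Dio3 cluster, the miR-29 and miR-30 families, and stress and inflammation. Markers of other cells covered erythroid cells, leukocytes, endothelium, stellate and smooth muscle cells, bile duct epithelium, and pancreas or muscle. Lists with at least 3 tested members entered camera with its preset correlation of 0.01, camera with an estimated correlation, and fry. Adjustment ran over 14 lists and 3 doses, 42 pairs in all. The directional p of fry asks whether the members of a list move one way on balance, its mixed p asks whether they change in either direction, and neither compares the list with other miRNAs.

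The miRNAs named in the text followed a rule. For each dose it took all that passed, at most 20, or the 8 with the smallest p where fewer than 8 passed. It also took up to 4 brightest tested members of each list, the 5 with the smallest p in the trend and F tests, and always miR-34a, miR-122 and miR-21. The tests, lists, naming rule and most alternatives were fixed before the data were examined. Any other miRNA in the text is said to have been chosen after its values were seen.

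The procedure was tested on simulated data of 208 miRNAs with the spread and slides of these arrays. At a 1.25-fold change it recovered 63.7, 59.9 and 61.8% of changed miRNAs at the low, middle and high doses, and at 1.5-fold it recovered 86.0, 84.2 and 85.9%. Of its calls, 3.76, 3.16 and 3.62% were false. With no change simulated, 8.67, 5.33 and 8.00% of 150 runs made any call. The simulated noise was independent between miRNAs, with no floor and no error of scaling. Each run changed 20 miRNAs at each of 1.25-, 1.5- and 2-fold, more than the 9, 12 and 5 called in the real comparisons. Many true changes ease the adjusted threshold, so recovery may be lower where fewer miRNAs change. Other splits of the real arrays called up to 17, 34 and 32 miRNAs at the 3 doses. The splits with 34 and 32 calls kept most dosed arrays together, so their counts are not rates of false calls. The simulated rates may still not hold for the real arrays. The list test made a call in 4% of 50 simulated runs without a change, whereas of 100 splits of the real arrays, the real one left aside, 95 made at least 1 list call (median 4), so the simulated rate does not hold for the real arrays. In the simulation it found a let-7 list raised 1.25-fold in 100% of runs.

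Alternatives were no slide term, the slide as a random block, a second block for the row of the slide, each slide left out, other background correction, other scalings, other summaries of a miRNA, the value table of the series, other filters, a floor 4 times higher, fits of 2 groups only, other variance models, array weights, other thresholds and each array left out. The planned normexp background correction (offset 50) was to use a mean spot signal, and the scanner files read here held a median spot signal, which was used instead. Scaling by labelling spike-ins and the signal of the array as a covariate were added after the data were seen. The array headers name the mouse build mm9 and the gene table at hand refers to another build, so no genome positions are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.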

Results

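Liver miRNA was measured in male MutaMouse animals, a transgenic strain that carries a reporter for mutations, after 28 daily oral doses of dibenz[a,h]anthracene. This polycyclic aromatic hydrocarbon binds the aryl hydrocarbon receptor and is turned into products that damage DNA. The groups received 0, 6.25, 12.5 or 25 mg/kg/day and are called control, low, middle and high dose, with 5, 5, 4 and 5 arrays, 1 per mouse. The question, from the series labels, was whether hepatic miRNAs respond to this exposure. Levels are log2 values relative to the 75th percentile of the array. Replicates of a group correlated at r of 0.961 to 0.997 across miRNAs, which are not independent replicates, and no arrays were identical.

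Array signal was compared between the groups. An array detected 200.6 ± 11.1 miRNAs (SD, n = 5) in controls, 194.6 ± 15.3 (SD, n = 5) at the low dose, 169.5 ± 11.1 (SD, n = 4) at the middle dose and 169.8 ± 12.7 (SD, n = 5) at the high dose. The exact permutation p against control was 0.0238 at the middle dose and 0.0159 at the high dose, and 0.0714 and 0.0635 after adjustment over 12 such comparisons. Within slides it was 0.0417, the smallest the 24 arrangements allow, and 0.0556, both 0.133 after adjustment. On slide 1 the control detected 181 miRNAs and the high dose arrays 180 and 184. The 75th percentile of signal was 357 ± 111 (SD, n = 5) in controls, 301 ± 74.6 (SD, n = 5), 215 ± 60.7 (SD, n = 4) and 195 ± 37.4 (SD, n = 5), with within-slide exact p of 0.167 and 0.0556 at the middle and high doses. RNA spiked in before labelling gave a log2 signal of 12.36 ± 0.24 (SD, n = 5) in controls and 11.52 ± 0.17 (SD, n = 5) at the high dose (exact permutation p = 0.00794, adjusted 0.0635). Within slides this high dose difference was -0.77 with an exact permutation p of 0.0278, the smallest the 36 arrangements allow, and 0.133 after adjustment. RNA spiked in at hybridization differed by -0.09 within slides (exact permutation p = 0.556). No measure passed after adjustment. For the labelling spike-ins both high dose p values were the smallest possible, so the number of arrays limited what could pass. All 5 high dose arrays (highest 11.78) lay below all 5 controls (lowest 11.97) in that signal. At the low dose the log2 signal differed by -0.24 within slides (exact permutation p = 0.317).

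**Figure D1:**
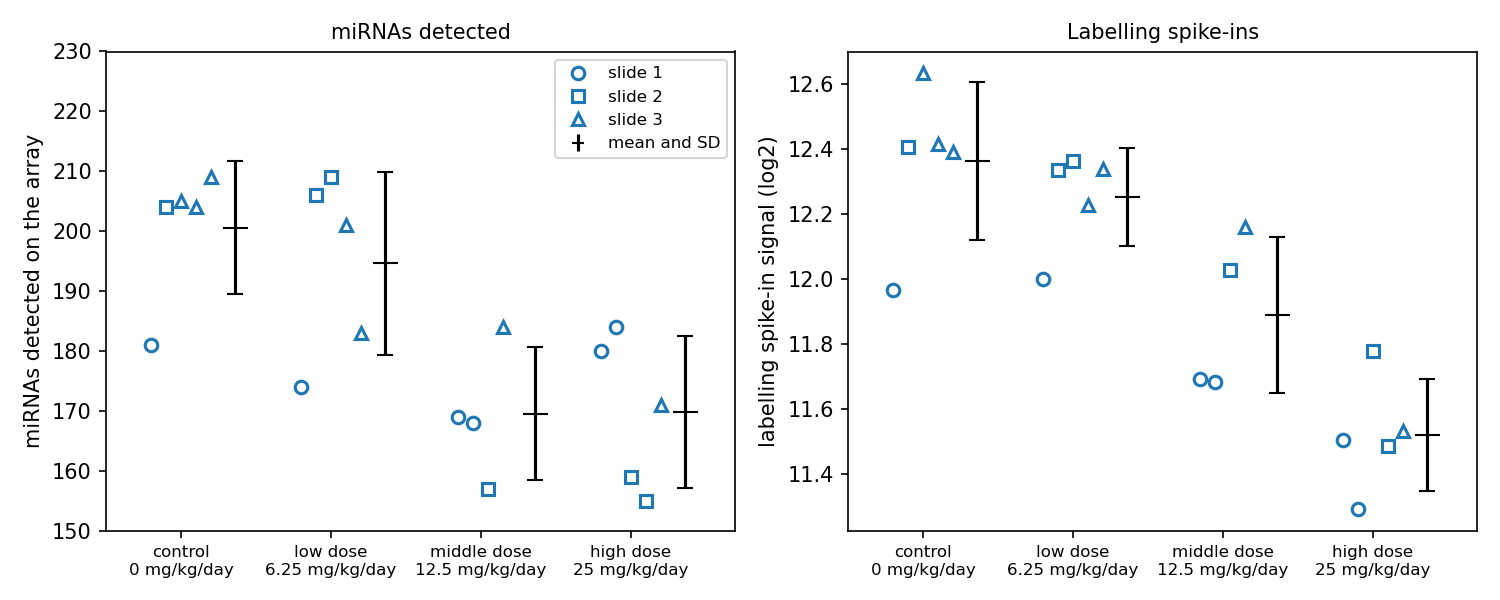
Number of miRNAs detected and log2 labelling spike-in signal of each array by dose group in mg/kg/day, with group means and SD. Each point is 1 array and its shape marks the slide. Controls averaged 200.6 detected miRNAs and the high dose arrays 169.8, while on slide 1 the control had 181 and the high dose arrays 180 and 184.

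Low dose against control asked which miRNAs respond to 6.25 mg/kg/day. miR-34a, a transcriptional target of p53 that restrains the cell cycle, rose 2.87-fold (95% interval 1.85 to 4.44; log2 1.52, SE 0.29), with all 5 dosed arrays above all 5 controls. miR-139-5p, found in endothelium and other cells, rose by 0.50 (SE 0.09) and miR-223, abundant in myeloid cells, by 0.37 (SE 0.09) on the log2 scale. The endothelial miR-126-3p rose by 0.29 (SE 0.07), and miR-20a and miR-20b of the miR-17 clusters, tied to cell division, by 0.27 each. miR-322 rose by 0.55 (SE 0.14), miR-10a by 0.21 and miR-23b by 0.20. miR-122, the most abundant hepatocyte miRNA, differed by 0.10 (adjusted p = 0.890) and miR-21, often raised in injured liver, by -0.08 (adjusted p = 0.998), and neither passed.

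In all, 9 of 208 miRNAs rose and 0 fell by limma; at an unadjusted p under 0.05 there were 28 higher and 0 lower, where chance gives 10.4. The adjusted p was 0.0165 for miR-34a, 0.0138 for miR-139-5p, 0.0382 for miR-223, 0.0268 for miR-126-3p and 0.0402 for miR-322 and miR-23b, and each of the 9 was higher than the control mean of its slide in 5 of 5 arrays. Slides 1 and 2 had 1 control each. Above all controls lay 5 of 5 arrays for miR-34a, miR-126-3p, miR-139-5p and miR-20b and 4 for miR-223. For miR-20a and miR-23b it was 3, for miR-322 2 and for miR-10a 1. The call of miR-34a was lost without control replicate 10 (adjusted p = 0.0692), and all 9 were lost there, while the count was 16 without control replicate 1, 14 without high dose replicate 15, 4 without control replicate 17, 3 without low dose replicate 18, and 2 without control replicate 19 or low dose replicate 3, 12 or 24. Under 3 other scalings (all probes, quantile, none) and with labelling spike-ins 0 miRNAs were called, and the 8 other than miR-34a stayed higher than control there. With the array signal as a covariate 7 of these 8 were kept, against 0 of the calls other than miR-34a at the middle and high doses, where all 11 and 4 stayed higher than control with medians of 0.24 (from 0.33) and 0.30 (from 0.43).

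Middle dose against control asked the same of 12.5 mg/kg/day. miR-34a rose 8.63-fold (95% interval 5.36 to 13.9; log2 3.11, SE 0.32) in 4 of 4 arrays, from a control level of -4.04 ± 0.22 (SD, n = 5) to -0.60 ± 0.71 (SD, n = 4). miR-23a and miR-27a, made from a shared precursor, rose by 0.34 and 0.38, miR-23b and miR-27b of the related cluster by 0.26 and 0.28, and miR-24 by 0.21. These 5 went the other way, below control, under all-probe scaling and without scaling. miR-92a and miR-93 of the miR-17 clusters rose by 0.34 and 0.24, and turned below control under the same 2 scalings. miR-139-5p rose by 0.51 (SE 0.10), miR-223 by 0.48 (SE 0.10), miR-15b by 0.33 and miR-652 by 0.32. miR-122 differed by 0.15 (adjusted p = 0.474) and miR-21 by 0.05 (adjusted p = 1).

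The counts were 12 of 208 higher and 0 lower by limma, against 45 and 7 at an unadjusted p under 0.05. The adjusted p was 3.59e-05 for miR-34a, 0.011 for miR-139-5p, 0.0198 for miR-223 and 0.0403 for miR-24, and all 12 were higher than the control mean of their slide in 4 of 4 arrays. Above all controls lay 3 of 4 arrays for miR-23b, miR-652 and miR-92a, 2 for miR-24, 1 for miR-93 and 4 for the others. The split of calls depended on the scaling: 1 higher and 35 lower with all probes, 1 and 8 with quantile normalization, 1 and 1 without scaling and 1 and 0 with labelling spike-ins, the 1 higher being miR-34a each time, and 2, miR-139-5p and miR-34a, were called with the slide and its row as blocks. Of the 11 others, 10 lay below control with all probes and 11 without scaling. Without control replicate 1 there were 40 calls, without control replicate 10 or middle dose replicate 6 or 14 there were 2, without low dose replicate 12 there were 6, and without control replicate 19 or 22 or middle dose replicate 20 there were 7.

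High dose against control asked the same of 25 mg/kg/day. miR-34a rose 11.2-fold (95% interval 7.12 to 17.6; log2 3.49, SE 0.30) in 5 of 5 arrays, to a level of -0.31 ± 0.53 (SD, n = 5). miR-139-5p rose by 0.47 (SE 0.09) in 5 of 5 arrays and miR-223 by 0.39 (SE 0.09) in 4 of 5, both against the control mean of the slide. miR-23b rose by 0.22 (SE 0.05) in 5 of 5 arrays against the control mean of the slide, and 4 of 5 lay above all controls. miR-1895 was called with controls at the floor, -4.79 ± 0.01 (SD, n = 5), so its change of 0.47 (SE 0.09) is set by the floor, and with a floor 4 times higher it was at 0 and not called (adjusted p = 1). Its probe was above background on 4 control arrays and on no middle dose array, although its middle dose level was higher (-4.54). Detection and level of miR-1895 thus went opposite ways at the middle dose. miR-30e at -0.38 (adjusted p = 0.065), miR-98 at 0.32 (adjusted p = 0.067) and miR-15b at 0.28 (adjusted p = 0.0578) did not pass, nor did miR-122 at 0.11 (adjusted p = 0.647) and miR-21 at -0.01 (adjusted p = 1).

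The counts were 5 of 208 higher and 0 lower by limma, against 41 and 12 at an unadjusted p under 0.05. The adjusted p was 4.88e-06 for miR-34a, 0.0111 for miR-139-5p and miR-1895, and 0.0482 for miR-223 and miR-23b. The split was 1 higher and 0 lower with all probes, 1 and 8 with quantile normalization, 1 and 69 without scaling and 25 and 0 with labelling spike-ins. With the slide and its row as blocks miR-34a alone was called, and with a floor 4 times higher miR-34a and miR-139-5p. The 4 others lay below control without scaling, as did miR-23b (-0.04) with all probes. Without control replicate 1 there were 27 calls, without high dose replicate 8 or middle dose replicate 14 there were 10, without middle dose replicate 20 there were 8, without high dose replicate 23 there were 2, and without low dose replicate 3, 12, 18 or 24, middle dose replicate 5, high dose replicate 15 or control replicate 22 there were 3.

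The median of all tested miRNAs shifted by 0.07, 0.11 and 0.06 at the low, middle and high doses. The shift was 0.02, -0.15 and -0.08 with all probes, -0.04, -0.24 and -0.47 without scaling, and 0.03, -0.00 and 0.14 with labelling spike-ins. Relative to the median of all tested miRNAs under the same scaling, the 8 low dose calls other than miR-34a lay above it in every one of these scalings. At the middle dose all 11 lay above it under the scaling used, with quantile normalization and with spike-ins, but 4 of 11 with all probes and 5 of 11 without scaling. At the high dose all 4 lay above it except without scaling, where 3 did. A scaling moves miRNAs at the floor less, so these counts depend on the floor. All 8, 11 and 4 calls, chosen for being high, lay above the median fold change of the 125 miRNAs never at the floor in each of these scalings.

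**Figure D2:**
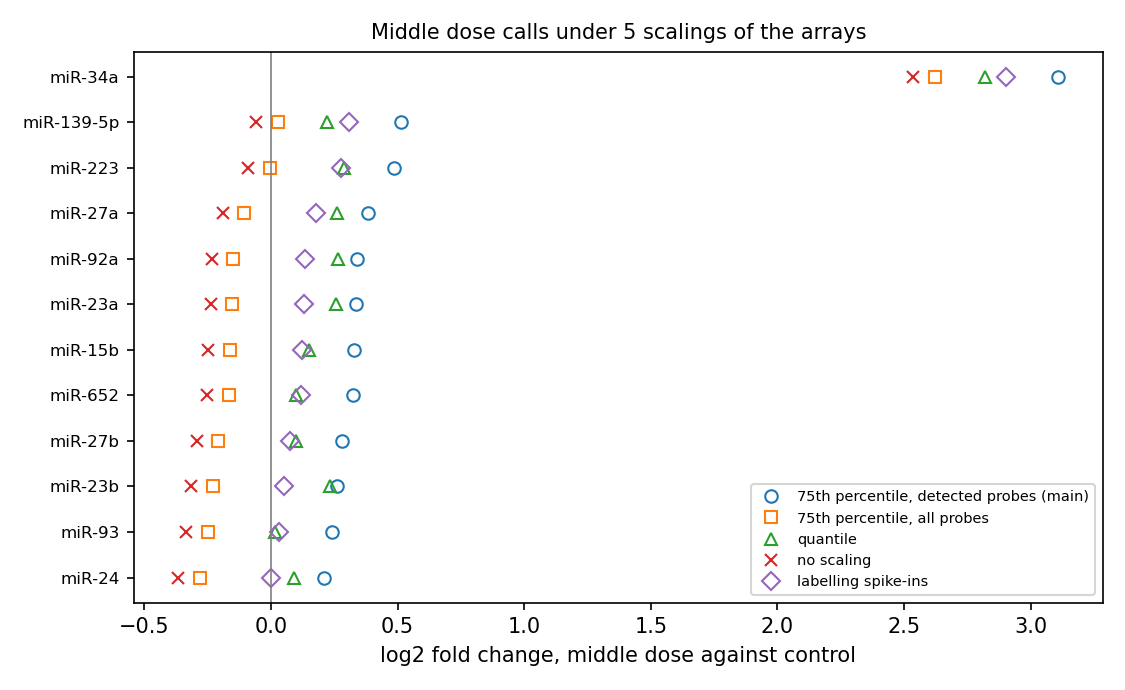
Log2 fold change of each miRNA called at the middle dose against control (12.5 mg/kg/day) under each scaling of the arrays, 4 dosed and 5 control arrays. miR-34a stays between 2.54 and 3.11, while 10 of the 11 others lie below 0 with all probes and 11 without scaling.

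The response of miR-34a was compared between doses. Its level was -4.04 ± 0.22 (SD, n = 5), -2.50 ± 1.00 (SD, n = 5), -0.60 ± 0.71 (SD, n = 4) and -0.31 ± 0.53 (SD, n = 5) from control to high dose. All 14 dosed arrays lay above the highest control (-3.75), with the lowest at -3.04, and the exact permutation p of each dose was 0.00794, the smallest possible. Within slides 1, 2 and 3 the difference from control was 3.04, 1.44 and 1.03 at the low dose, 3.58, 3.86 and 2.44 at the middle dose and 3.92, 3.63 and 3.49 at the high dose. The middle dose exceeded the low dose by 1.59 (95% interval 0.91 to 2.27, adjusted p = 0.0407) and the high dose exceeded it by 1.97 (1.33 to 2.60, adjusted p = 0.00257). The high and middle doses differed by 0.38 (-0.29 to 1.04, adjusted p = 0.909). Low dose replicate 3 stood at -0.71, and without it the low dose change was 1.21 (adjusted p = 0.0307). At the middle and high doses each slide alone had a control or dose group of 1 array, so only differences are given for single slides. In the fits with more than 1 slide the middle and high dose calls held under every alternative tried, and 11 of 23 alternatives other than left-out arrays kept the low dose call. The size moved with the processing: the fold changes at the low, middle and high doses were 1.72, 3.09 and 3.60 with the normexp background, 1.56, 2.94 and 3.69 in the value table of the series and 1.31, 3.73 and 4.80 with a floor 4 times higher. Of the 2 probes for miR-34a, the other one gave 1.42, 2.98 and 3.38 at the 3 doses.

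**Figure D3:**
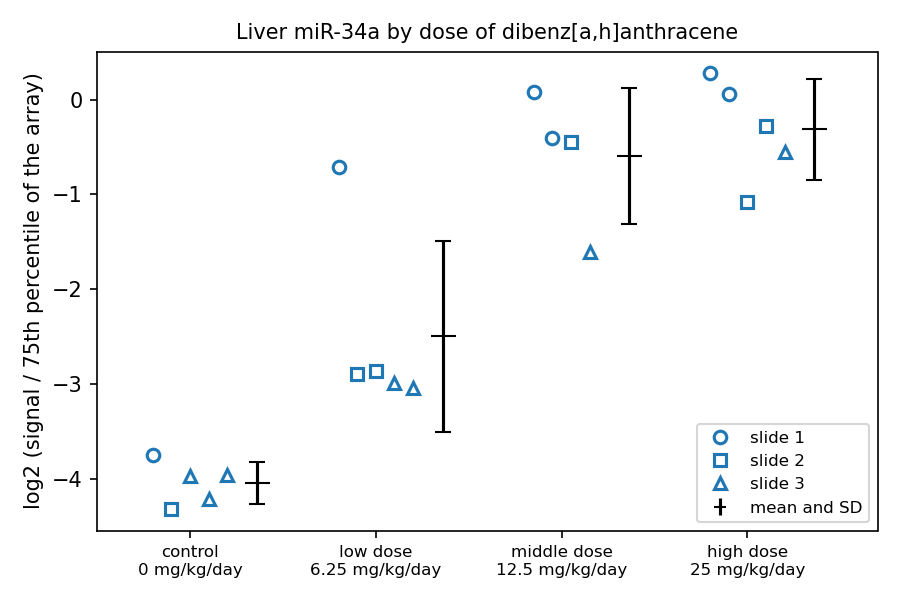
Log2 level of miR-34a relative to the 75th percentile of the array, by dose in mg/kg/day; each point is 1 mouse, shapes mark the slide, and the bars are means and SD. The controls lie at or below -3.75, and low dose replicate 3 lies at -0.71, above the other 4 low dose arrays.

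The comparisons over all doses asked for any dose effect. The F test called miR-34a (adjusted p = 2.18e-05) and miR-139-5p (adjusted p = 0.0151), and miR-223, miR-1895 and miR-23b followed at 0.0643 and did not pass. The trend called miR-34a, at 0.13 log2 per mg/kg/day (SE 0.0185, adjusted p = 0.00052), and miR-1895, with controls at the floor, at 0.02 (adjusted p = 0.00572). With a floor 4 times higher the trend called 1 miRNA and miR-1895 was at 0 at each dose. Of the others in the trend, miR-30e (adjusted p = 0.0564), miR-29a and let-7b* (both 0.0839) did not pass. The mean of the doses against control called 17 miRNAs, all higher, among them miR-34a at 2.70 (adjusted p = 9.89e-06), miR-139-5p at 0.50 (adjusted p = 0.00136), miR-223 at 0.42 and miR-23b at 0.23 (both adjusted p = 0.00838). Unadjusted counts were 52, 48 and 51. With the slide and its row as blocks the 3 tests called 2, 1 and 2 miRNAs, and with all-probe scaling 6, 1 and 1.

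These 3 counts also moved with single arrays. The F test gave 21 without control replicate 1, 13 without high dose replicate 15, 6 without middle dose replicate 14, 5 without high dose replicate 7, 4 without low dose replicate 11, high dose replicate 16 or middle dose replicate 20, and 1 without control replicate 10, 17 or 22. The trend gave 17 without high dose replicate 8, 6 without control replicate 10, 5 without control replicate 19, 4 without middle dose replicate 14 and 1 without high dose replicate 23. The mean of the doses gave 39 without control replicate 1, 2 without control replicate 10, 7 without control replicate 17 or low dose replicate 24, 9 without control replicate 19, and 10 without control replicate 22, low dose replicate 18 or middle dose replicate 6.

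miR-34a, miR-139-5p, miR-223 and miR-23b were called at all 3 doses, and miR-34a alone with the slide and its row as blocks. All 9, 12 and 5 calls of the 3 doses were higher than control within each of the 3 slides. Each pair of doses shared 4 calls, where independent lists would share 0.519, 0.216 or 0.288 for low and middle, low and high, and middle and high. The doses share the same controls, and simulations of shared controls with no effect gave a mean of 0 shared calls in 100 runs. Simulated runs without a change seldom made any call (5.33 to 8.67% at a single dose), so this 0 was nearly fixed in advance. It does not show whether shared controls add to the 4 shared calls. With the controls split between the doses, in 20 splits, the median number shared was 0, 0 and 1 and the highest 2, and miR-34a was shared in 8, 8 and 20 splits. Fold changes of the doses correlated across miRNAs at 0.744, 0.71 and 0.839, against 0.474, 0.470 and 0.476 from shared controls alone, simulated with noise independent between miRNAs. These correlations include miR-34a, at 1.52, 3.11 and 3.49, where the highest other call was at 0.55, 0.51 and 0.47. No correlation without miR-34a is given, so a response shared across other miRNAs is not shown by this excess.

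Among the fixed lists, the p53 response had 7 tested members of 13, and miR-34a was the 1 that rose at each dose, over all miRNAs and adjusted over the list alone; at the high dose 1 more, adjusted over the list alone, fell. Its other members included miR-192, the hepatocyte miRNA that p53 can induce, at 0.08, -0.01 and 0.05, and miR-194 at 0.04, -0.06 and -0.08. The 4 mature forms of miR-34b and miR-34c were not detected on any array. camera gave the list adjusted p = 0.965, 0.859 and 0.419; its mean was 0.54 at the middle and 0.45 at the high dose while its median was -0.01 and -0.05 and the test direction downward.

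The miR-29 and miR-30 families, regulators of matrix genes and epithelial state, lay lower than other miRNAs by camera at the middle (adjusted p = 0.00221) and high dose (adjusted p = 0.00198), but not with an estimated correlation (adjusted p = 0.536 for both). The list had medians of -0.09 and -0.13 over 8 members and these signs under all scalings tried. The list did not pass with quantile normalization (0.135 and 0.0687) or labelling spike-ins (0.0616 and 0.0696). At the low dose the preset gave 0.331 with a mean of -0.00 and a median of 0.02. No member passed over all miRNAs; adjusted over the list alone, 3 were lower at the high dose. miR-29a was at -0.17 and miR-30a at -0.28 at the high dose (adjusted p = 0.10 and 0.092). The hepatocyte list of 11 tested members lay lower at the middle dose (adjusted p = 0.00198; adjusted p = 0.536 with an estimated correlation), with a median of -0.06, and passed under all scalings tried (highest adjusted p = 0.0492). Its adjusted p was 0.190 and 0.0534 at the low and high doses, and 0 members were called at any dose by limma; adjusted over the list alone, 1 was higher and 4 were lower at the high dose. miR-148a was at -0.15 and -0.18 at the middle and high doses (adjusted p = 0.189 and 0.103).

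The endothelial markers lay higher at the low dose (adjusted p = 0.00198; adjusted p = 0.352 with an estimated correlation), with a median of 0.29 and upward under all scalings tried, but did not pass with all probes (0.0600), without scaling (0.153) or with labelling spike-ins (0.0696). Of 3 tested members miR-126-3p and miR-139-5p rose, also adjusted over the list alone, and miR-126-5p, near the floor, was at 0.05. At the middle and high doses 1 member rose (adjusted p = 0.365 and 0.432 for the list). The miR-17 clusters lay higher at the low dose (adjusted p = 0.00214; adjusted p = 0.536 with an estimated correlation), with a median of 0.13 that was -0.02 without scaling, and did not pass under the 4 other scalings (lowest adjusted p = 0.147). Of 9 tested members 2, 2 and 0 rose at the 3 doses, and 3, 3 and 0 adjusted over the list alone, with list p of 0.190 and 0.432 after adjustment at the middle and high doses. miR-19b was at 0.18 and miR-106b at 0.11 at the low dose and did not pass.

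The other lists did not pass camera at any dose. Of 7 tested members of the aryl hydrocarbon receptor list, 1, 3 and 1 rose, and 3, 3 and 1 adjusted over the list alone; miR-23b was called at each dose and miR-24 and miR-27b at the middle dose (list adjusted p = 0.0720, 0.211 and 0.578). The let-7 family, which restrains growth genes, had 0 of 9 called, and 0, 1 and 1 higher adjusted over the list alone (0.190, 0.534 and 0.331); let-7a was at 0.15, 0.15 and 0.18 and let-7c at 0.17, 0.19 and 0.15. The liver tumour list had 0 of 5 called, also adjusted over the list alone (0.859, 0.401 and 0.419), with miR-221 at 0.17, 0.04 and 0.02 and miR-96 at 0.60, 0.58 and 0.47. The Dlk1-Dio3 cluster had 3 of 31 members tested and 0 called, also adjusted over the list alone (0.419, 0.534 and 0.859); miR-409-3p was at -0.06, 0.28 and 0.36 and miR-494 at 0.12, 0.88 and 0.31. In stress and inflammation, miR-34a and miR-223 rose at each dose among 7 tested members, also adjusted over the list alone, where 1 other was lower at the high dose (0.331, 0.419 and 0.554). miR-125b-5p there was at 0.08, 0.19 and 0.03, and miR-203 at 0.01, -0.11 and -0.26.

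Among the other cell markers, miR-15b rose at the middle dose in the erythroid list of 4, and 1 was higher at each dose adjusted over the list alone (0.959, 0.859 and 0.419); miR-451 was at 0.04, -0.05 and -0.28 and miR-144 at 0.10, -0.17 and -0.34. Of 5 tested leukocyte markers miR-223 rose at each dose, also adjusted over the list alone (0.190, 0.554 and 0.534), with miR-142-3p at 0.19, 0.20 and 0.12 and miR-146a at 0.28, 0.17 and 0.15. The stellate and smooth muscle list had 0 of 7 called, also adjusted over the list alone (0.876, 0.280 and 0.280), with miR-143 at 0.13, 0.83 and 0.10 and miR-199a-3p at 0.17, 0.28 and -0.07. Bile duct epithelium had 0 of 7 called, also adjusted over the list alone (0.755, 0.190 and 0.280), with miR-200a at 0.60, 0.22 and 0.19 and miR-31 at -0.04, -0.31 and -0.33. Pancreas or muscle had 2 tested members, miR-1 and miR-133b, and no list test; neither passed.

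With camera's preset correlation 5 of 42 pairs passed, and with an estimated correlation 0 passed. By fry 8 pairs passed, all upward: the aryl hydrocarbon receptor list at the low and middle doses, the miR-17 clusters at the low dose, the endothelial markers at the low and middle doses, the Dlk1-Dio3 cluster at the middle dose, and stress and inflammation at the middle and high doses. camera's direction was downward while median and mean were above 0 for bile duct epithelium at each dose and the liver tumour list at the middle dose. It was also downward with a median of 0 and a mean above 0 for the liver tumour list at the low and high doses and the Dlk1-Dio3 cluster at the low dose. For erythroid cells at the middle dose the mean was 0.03 and the median -0.02. Without control replicate 1 there were 3 passing pairs and without control replicate 19 there were 8.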

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

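The tests of scaling, slide and probe for miR-34a at the middle and high doses, of scaling and signal for the other calls, and of a swap, the slide and epithelial tissue for low dose replicate 3 were chosen after the result was seen. The remaining tests were set before it.

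The change of miR-34a differed between doses, by a test of the difference itself: 1.59 more at the middle and 1.97 more at the high dose than at the low dose, in limma. Its rise at the middle and high doses was not produced by the scaling, since the lowest value over 4 other scalings was 2.54 (highest adjusted p = 0.00256). Slides do not account for it either, the lowest difference within a slide being 2.44, nor does a single faulty probe, since the other probe saw at least 0.958 of the change. As a hypothesis, found and tested on the same data, the rise may be a response to the compound that grows between the low and middle doses.

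For the 9, 12 and 5 calls at the 3 doses 2, 2 and 3 of 100 splits, the real one included, gave as many and the highest other split gave 17, 34 and 32. For the 2 calls of the F test it was 3 of 100 splits (highest other 9), for the 2 of the trend 2 of 100 (highest other 3) and for the 17 of the mean of the doses 1 of 100 (highest other 7). These splits mixed arrays between slides. With arrays exchanged only within slides, a test added after the result, 1 of 60, 1 of 24 and 2 of 36 arrangements gave as many at the low, middle and high doses (highest other 2, 1 and 32), and of 100 arrangements 5 did in the F test, 1 in the trend and 1 for the mean of the doses. Unadjusted, the share was under 0.05 at the low and middle doses, in the trend and for the mean of the doses. At the middle dose 0.0417 was the smallest share possible. These shares concern counts under the scaling used and do not exclude chance for single calls. Chance also stays open for the number of calls at the high dose (share 0.0556) and in the F test (share 0.05). The change of miR-34a was largest in the real arrangement at each dose. Some splits called several times the real count, which points to a structure of the samples. The split with 34 calls set control replicate 1 with the 4 middle dose arrays against the other 4 controls, none of which was on slide 1, and the split with 32 exchanged control replicate 1 with high dose replicate 8, both on slide 1. Control replicate 1 is the only control of slide 1, so the array and the slide cannot be told apart here. For the list pairs, chance cannot be excluded: 40 of 100 splits gave as many as the real 5, the highest other split gave 10, and within slides it was 42 of 100.

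Small rises made up the other 23 calls over the 3 doses, of 17 miRNAs, and at most 0 of them passed under any of the other 3 planned scalings. Where the 15 calls of the middle and high doses went from a median of 0.34 (median SE 0.0836) to -0.25 (median SE 0.22) without scaling, the miRNAs above the floor of an array moved together, so the turn in sign decides nothing. With each array set relative to its 125 miRNAs that were never at the floor, the choice of scaling stays open at the middle and high doses, where under the scaling used the median call was at 0.0233 (median SE 0.0961), the lowest over 4 scalings, with their median as reference (11 of 15 higher than control) and at 0.13 (median SE 0.0819) with their mean (15 of 15). It stays open too at the low dose, with 0.0671 (median SE 0.0873, 6 of 8 higher) and 0.15 (median SE 0.0710, 8 of 8) against 0.28 (median SE 0.0659) before. With quantile normalization the 2 references gave higher values. These were 0.17 (median SE 0.0998, 14 of 15 higher) and 0.24 (median SE 0.0904, 15 of 15) at the middle and high doses. At the low dose they were 0.12 (median SE 0.0909, 7 of 8) and 0.16 (median SE 0.0665, 8 of 8). Dimmer arrays at the middle and high doses remain open: with the array signal as a covariate, the median of 15 calls moved from 0.34 (median SE 0.0836) to 0.24 (median SE 0.0910), a ratio of 0.702, while at the low dose it was 0.28 both ways.

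In low dose replicate 3 miR-34a stood at -0.71, far above the other 4 arrays of its group (-3.04 to -2.86). A swap with a middle or high dose sample needs a partner out of place, and the lowest of those arrays lay 1.249 above these 4 (their SD 0.0830). The labels describe 5 animals per dose and 4 middle dose arrays were analysed, so a swap with a middle dose sample not analysed stays open. The control of slide 1 lay 0.21 above the highest other control, so that slide did not raise its control by as much. This rests on 1 control, and replicate 3 is the only low dose array there, so a slide effect on dosed arrays is not excluded. A faulty probe does not account for the level, as the other probe lay 2.11 above the other 4 arrays. A single wrong label remains open, since the labelling spike-in signal was 12.0, inside the range of the middle and high dose arrays (11.29 to 12.16), though above all 5 high dose arrays (highest 11.78) and above all 4 middle and high dose arrays of its own slide (highest 11.69), whose control was at 11.97. So does more epithelial tissue, where the level predicted for high dose replicate 8 exceeded the measured one by 0.80 (SD of the other 4 arrays 0.56), which rests on a single array; a stronger response of this mouse was not tested.

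Single arrays that stood far from the rest of their group, by the gap to the nearest value relative to the range of the group, were found in 21 of 235 groups of values, where chance gives about 1 in 20, or 11.75. This count does not allow for the slide, and 13 of the 21 fell on control replicate 1 or low dose replicate 3, each the only array of its group on slide 1. Control replicate 1 held let-7f at 3.58, miR-106b at -1.61, miR-122 at 6.82 and miR-192 at 3.40. Its log2 hybridization spike-in signal of 14.25 was a level of slide 1, whose arrays had 14.01 to 14.34, against 14.50 to 15.18 on the other slides. Its 181 detected miRNAs lay in the range of slide 1, 168 to 184, but the other slides had 155 to 209, so that number does not set slide 1 apart. Low dose replicate 3 held, besides miR-34a, let-7g at 2.30, miR-125b-5p at -0.41, miR-194 at 0.34, miR-200a at -0.90, miR-200b at -0.97 and miR-30e at -1.58. High dose replicate 8 held miR-143 at -1.92, miR-199b* at -3.46, miR-200a at 0.0246 and miR-200b at 0.00023. The others were let-7b* at -2.62 in high dose replicate 16, miR-1 at 0.74 in middle dose replicate 20, miR-142-3p at -0.52 in middle dose replicate 5 and miR-30a at 0.92 in low dose replicate 24.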

How the results depend on the processing

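Counts of calls are given in the order low dose, middle dose, high dose, F test, trend, mean of the doses and list pairs, and were 9, 12, 5, 2, 2, 17 and 5. Scaling by labelling spike-ins and the signal of the array as a covariate were chosen after the data were seen. For the slides, no slide term gave 3, 12, 19, 8, 16, 17 and 5, a random block 8, 12, 10, 8, 2, 22 and 5, and blocks for the slide and its row 8, 2, 1, 2, 1, 2 and 5. Leaving out slide 1 gave 12, 13, 39, 12, 30, 31 and 3, leaving out slide 2 gave 0, 3, 10, 4, 9, 7 and 6, and leaving out slide 3 gave 0, 1, 1, 1, 0, 1 and 5. Among scalings, the 75th percentile over all probes gave 0, 36, 1, 6, 1, 1 and 4, quantile normalization 0, 9, 9, 6, 9, 13 and 3, no scaling 0, 2, 70, 9, 105, 6 and 4, and labelling spike-ins 0, 1, 25, 22, 27, 16 and 1. The signal of the array as a covariate gave 8, 1, 2, 1, 2, 3 and 7. For the signal, the normexp background gave 0, 1, 1, 1, 1, 1 and 7, the total signal per miRNA 0, 11, 8, 8, 3, 8 and 4, the mean over all probes 9, 10, 6, 3, 3, 16 and 6, and the value table of the series 2, 7, 14, 2, 20, 11 and 0. Not all calls were higher under these settings. With the total signal, 1 call was higher and 10 lower at the middle dose, and 2 and 6 at the high dose. In the value table it was 3 and 4, and 11 and 3, at the same doses. With slide 2 left out it was 1 and 2, and 2 and 8. A filter for detection on all arrays gave 7, 13, 10, 4, 6, 19 and 4, no filter 0, 2, 3, 1, 2, 4 and 17, and a floor 4 times higher 6, 8, 2, 2, 1, 11 and 9. In the models, fits of only the 2 groups compared gave 8, 2 and 2 for the doses and 4 list pairs, eBayes with trend and robust 9, 12, 3, 2, 2, 17 and 5, and array weights 14, 26, 36, 30, 22, 41 and 5. Adjusted p under 0.10 gave 14, 20, 14, 13, 23, 25 and 7. A change of at least 1.5-fold left 1 miRNA at each dose and 1 for the mean of the doses, and has no meaning for the F test, trend and lists. Of the list tests, camera with an estimated correlation gave 0 pairs and fry 8. Leaving out 1 array at a time gave 0 (control replicate 10) to 16 (control replicate 1) at the low dose, 2 (control replicate 10, middle dose replicate 6 or 14) to 40 (control replicate 1) at the middle dose and 2 (high dose replicate 23) to 27 (control replicate 1) at the high dose. It gave 1 (control replicate 10, 17 or 22) to 21 (control replicate 1) in the F test, 1 (high dose replicate 23) to 17 (high dose replicate 8) in the trend, 2 (control replicate 10) to 39 (control replicate 1) for the mean of the doses and 3 (control replicate 1) to 8 (control replicate 19) list pairs; the other arrays that moved a count by over 1.5 times are named in the report with their values. The cause was not tested for these differences between settings, apart from the scaling tests given with the patterns above.

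Directions turned under some settings. At the middle dose without scaling, miR-139-5p was at -0.0601, miR-15b at -0.25, miR-223 at -0.0907, miR-23a at -0.24, miR-23b at -0.32, miR-24 at -0.37, miR-27a at -0.19, miR-27b at -0.29, miR-652 at -0.25, miR-92a at -0.23 and miR-93 at -0.34. With the 75th percentile over all probes, miR-15b was at -0.16, miR-223 at -0.00519, miR-23a at -0.15, miR-23b at -0.23, miR-24 at -0.28, miR-27a at -0.11, miR-27b at -0.21, miR-29c at -0.49, miR-652 at -0.17, miR-92a at -0.15 and miR-93 at -0.25. In the value table of the series, miR-93 was at -0.0405. At the high dose without scaling, let-7a was at -0.52, let-7c at -0.55, let-7f at -0.58, miR-122 at -0.60, miR-139-5p at -0.23, miR-1895 at -0.11, miR-192 at -0.66, miR-223 at -0.32, miR-23b at -0.48, miR-24 at -0.67 and miR-93 at -0.62, and with all probes miR-23b was at -0.0434. Of these, let-7a, let-7c, let-7f, miR-122, miR-192, miR-24 and miR-93 at the high dose and miR-29c at the middle dose passed limma downward under that setting and did not pass upward in the scaling used.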

Other observations

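The miR-200 family, of epithelial cells, was high in 4 arrays from 3 dose groups. miR-200a, which keeps epithelial cells in their state, stood at -0.90 in low dose replicate 3, -1.43 in middle dose replicate 6, -2.10 in middle dose replicate 14 and 0.02 in high dose replicate 8, and between -4.32 and -3.02 in the other 15 arrays. Its cluster partner miR-200b stood at -0.97, -1.37, -1.85 and 0.00023 in these 4 arrays. Related members chosen after their values were seen followed: miR-429 at -2.70, -3.30, -4.00 and -1.76, and miR-200c at -3.03, -2.91, -3.79 and -1.76, with every other array at the floor of -4.79 for both. Other epithelial miRNAs did not follow: miR-203 stood at -3.82, -3.74, -3.41 and -4.12 in these 4 arrays and miR-31 at -3.46, -3.59, -3.67 and -3.92. The labels describe the tissue as part of a liver and do not name the lobe. No dose group passed the test for miR-200a or miR-200b.

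Muscle miRNAs were high in 3 other arrays, from 3 groups. miR-1, a miRNA of heart and skeletal muscle, stood at 1.71 in low dose replicate 11, 0.74 in middle dose replicate 20 and 1.19 in control replicate 22, and at or below -2.67 in the other 16 arrays. miR-133b stood at -0.20, -0.98 and -0.68 in the same 3 arrays and at or below -4.12 elsewhere, and miR-133a, chosen after its values were seen, at -1.29, -1.98 and -1.81. miR-143, of smooth muscle and stromal cells, was -1.64 in middle dose replicate 20, -1.65 in middle dose replicate 14 and -1.92 in high dose replicate 8. miR-145, a marker of the same cells chosen after its values were seen, did not follow. It was at the floor and not detected on any array.

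RNA spiked in before labelling averaged 12.36, 12.25, 11.89 and 11.52 on the log2 scale from control to high dose. RNA spiked in at hybridization averaged 14.79, 14.85, 14.68 and 14.54. No difference from control passed after adjustment in the exact permutation tests, where the p of the labelling spike-ins at the high dose was the smallest possible.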
